A study of Mus musculus with 8 samples.

How the data were processed

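Poly(A)-selected RNA from mouse embryonic stem cells (ES cells) and from day 2 embryoid bodies (EBd2, aggregates in which ES cells begin to differentiate) was sequenced in 8 libraries. Per the labels, 4 libraries carry floxed, undeleted Skp1a (fl/fl) and 4 are knockouts (KO) of Skp1a, which encodes the adaptor of SCF ubiquitin ligases that joins CUL1 to F-box proteins. Each of the 4 groups of genotype and stage holds 2 libraries, numbered by lots 1, 2 and 12. Whether the lots are separate cultures, clones or preparations is not given in the sources used here. The tissue field calls all KO libraries ES cells and all fl/fl libraries embryoid bodies, which conflicts with the sample titles. Groups follow the titles, and stage markers were checked in each library. RNA was purified on spin columns and selected with poly(A) magnetic beads, per the labels.

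The deposited table holds raw counts of reads per gene symbol for 36255 genes, of which 9800 have 0 counts in all libraries. Its values are whole numbers with no normalization. Per the submitters' processing notes, Trim Galore 0.6.7 and the builds GRCm38 and mm10 were used. The aligner, the counting tool, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Of the symbols, 34777 (95.9%) matched the GENCODE vM21 annotation once. Among genes with at least 1000 counts, 8 had counts identical to those of another gene in every library. Values of genes with near-identical copies (Zscan4, Sprr2a, Rhox and histone genes) are uncertain for that reason. 5 noncoding genes of the imprinted list are not in the table.

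Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the 4 groups, which left 16542 genes, and libraries were scaled by TMM factors. A model with 4 group means was fitted to all 8 libraries, so that the spread between libraries was shared across groups that hold 2 each. The edgeR quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) was applied to 5 contrasts. These were KO against fl/fl in ES cells, KO against fl/fl in EBd2, EBd2 against ES cells in fl/fl, EBd2 against ES cells in KO, and the interaction of genotype and stage. All adjusted p values of single genes come from this test with the Benjamini-Hochberg (BH) correction over all 16542 genes, at a threshold of 0.05. The common biological coefficient of variation was 3.4%, with 4 residual and 7 prior degrees of freedom. Such a low spread means that p values measure only the spread between these libraries, which may be technical. Differences between clones or derivations of the lines are not covered by them.

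30 gene lists were tested. They hold naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, mesoderm, primitive and visceral endoderm, neuroectoderm, trophectoderm, two-cell-like and germline genes. Others hold the Hox clusters, other developmental regulators held by Polycomb in ES cells, subunits of PRC2 and of PRC1 (Polycomb repressive complexes), and SCF partners of SKP1. Targets of p53, Wnt, NF-kappaB and NRF2, cholesterol synthesis, G1/S and E2F targets, G2/M, hypoxia and glycolysis, integrated stress and unfolded protein response, interferon response and imprinted genes were also listed. The last lists hold markers of fibroblast feeder cells, replication-dependent histones, which lack a poly(A) tail, mitochondrially encoded transcripts and ribosomal proteins. For each list the called members were counted with adjustment over all genes and with adjustment over the list alone. Lists were compared with all other genes by camera (limma 3.58.1) on log2 CPM (counts scaled to a common library size) with a prior count of 2. The camera test was run with a preset correlation of 0.01 between genes and with a correlation estimated from the data. Its p values were adjusted by BH over the 30 lists of a contrast. With an estimated correlation camera has only the 4 residual degrees of freedom, so calls can be lost through low power alone. The histone list in ES cells had an estimated correlation of -0.0067, below the preset, yet its camera p went from 1.17e-06 to 0.00448. A call that did not hold in that run is therefore not evidence against a change. The fry test, which asks whether members move on balance one way and does not compare a list with other genes, was run on the same log2 CPM.

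The genes named were chosen by rule. Skp1a came first, followed by the 6 genes with the largest rise and the 6 with the largest fall among those called. These had to reach a mean of 5 CPM in the higher group, with both libraries of one group above both of the other, and genes without a proper name were passed over. From each list, up to 4 called members with the smallest p were added. Ezh2, Eed, Suz12, Jarid2, Kdm2b, Pcgf1, Pou5f1, Nanog, Zfp42, Fgf5, Otx2, T, Gata6, Cdkn1a, Ccne1 and Cdkn1b were eligible whatever their p, and Klf4 and Pou3f1 were added as markers of the stage labels. Some genes that the rule selects are not reported here, fewer were named where space required, and any gene outside the rule is said to be so. The groups, contrasts, tests, gene lists and this rule, and most of the alternatives, were chosen before the data were examined.

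Folds against a group with 0 counts are lower bounds against a floor of 3 counts summed over the group's 2 libraries. With 1 to 3 counts in the lower group, the ratio is given with an exact 95% interval for the counts. Over the 2 libraries of a group and after TMM scaling, that floor equals 0.0702 CPM in fl/fl ES cells, 0.0682 CPM in ES cells labelled KO, 0.187 CPM in fl/fl EBd2 and 0.14 CPM in EBd2 labelled KO. Intervals and floors cover counting error only.

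Alternatives were scaling by median-of-ratios (RLE) factors or by library size only, no filter or a stricter filter (5 CPM in 2 libraries), and DESeq2 1.42.0. Fits of only the 4 libraries compared, fits without each library in turn and fits with lots as blocks were also run. After the data had been seen, 4 alternatives were added: library size only, a test for changes beyond 1.5-fold (glmTreat), a fit without pseudogenes and mitochondrial genes, and thinning of all libraries to the smallest total. The lots could not be used to pair libraries, since the deviations of lot 1 libraries correlated between groups at only -0.022 to 0.018 across genes. The procedure was tested on simulated data, 10 draws of 8 libraries with the observed dispersions, 500 changed genes per fold and genotype comparison over all draws, and a mean of 15680 genes tested. In the ES cell comparison, 44.2% of genes changed 1.25-fold were recovered, 69.8% at 1.5-fold, 81.4% at 2-fold and 94% at 4-fold. In EBd2 the shares were 31.6% at 1.25-fold, 57.8% at 1.5-fold, 69.6% at 2-fold and 87% at 4-fold. False calls were 12.5% of all calls in ES cells and 7.31% in EBd2, above the nominal 5%. Of unchanged genes, 0.134% were called in ES cells and 0.0627% in EBd2. Only 2000 genes were changed per comparison over all 10 draws, while the data gave 3926 calls in ES cells and 10289 in EBd2. Recovery and the share of false calls depend on how many genes change, so neither carries over to the real calls. A seeded list of 20 genes raised 1.5-fold in EBd2 had 9 members called, 12 over the list alone, with camera p = 4.67e-17, or p = 0.000786 with an estimated correlation. A list of unchanged genes was not called by camera. Both lists came from a single draw with genes simulated independently. They therefore do not show how often camera calls unchanged lists of correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, using numpy 2.4.6 and pandas 2.3.3.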

Results

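RNA from 2 libraries in each of 4 groups was counted per gene. The groups were fl/fl ES cells, ES cells labelled KO, fl/fl EBd2 and EBd2 labelled KO. The question stated by the series is how expression differs between Skp1 wild-type and knockout cells, in ES cells and in embryoid bodies, and its title concerns turnover of the Polycomb complex PRC2 and the activation of genes silenced by Polycomb. Total counts were 23343471 and 21545868 in fl/fl ES cells and 22459935 and 21559558 in ES cells labelled KO. In EBd2 they were lower, at 7858452 and 9133497 in fl/fl and 9260644 and 10055667 in KO. Mitochondrial transcripts took 1.76% and 1.73% of counts in fl/fl ES cells and 2.43% and 2.42% in ES cells labelled KO. Their share was 2.7% and 2.28% in fl/fl EBd2 and 3.15% and 3.24% in EBd2 labelled KO. Fold changes below are log2 values ± standard error, with n = 2 libraries per group throughout. That error is the absolute log2 fold change divided by the square root of the test's F statistic. It rests on the spread shared across groups, and is approximate for large folds and low counts.

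Skp1a (chromosome 11, 52231995 to 52246858, + strand, GRCm38), the targeted gene, was lower in the libraries labelled KO but kept most of its level. Its TMM-scaled level was 425.2 ± 7.19 CPM (SD, n = 2) in fl/fl ES cells and 365.1 ± 5.35 CPM in ES cells labelled KO. In EBd2 it was 395.3 ± 8.74 CPM in fl/fl and 287.7 ± 2.67 CPM in KO. The level left was thus 85.9% of fl/fl in ES cells (-0.22 ± 0.03, edgeR adjusted p = 0.00073) and 72.8% in EBd2 (-0.46 ± 0.04, adjusted p = 5.13e-07). Counts per gene cannot show whether exons were deleted, so the genotype is called by its label here. A test for changes beyond 1.5-fold called Skp1a at neither stage, with adjusted p = 1 in both. Both estimates are smaller than 1.5-fold, so that test could not call the gene.

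Stage markers sided with the sample titles in fl/fl cells, while in cells labelled KO some did so and others barely moved. Fgf5, which marks the formative epiblast, was at 0.538 ± 0.00117 CPM (SD, n = 2) in fl/fl ES cells and 0.585 ± 0.434 CPM in ES cells labelled KO, against 55.7 ± 2.01 CPM in fl/fl EBd2 and 20.3 ± 0.279 CPM in EBd2 labelled KO. Klf4, a naive pluripotency factor, was at 155.8 ± 1.43 CPM in fl/fl ES cells and 109.4 ± 3.12 CPM in ES cells labelled KO, against 12.7 ± 1.57 CPM and 41 ± 2.05 CPM in the corresponding EBd2. The epiblast factor Otx2 stood at 88.8 ± 10.3 CPM in fl/fl EBd2 and between 9.52 and 10.7 CPM in the other 3 groups. Pou3f1 was at 12.8 ± 1.19 CPM in fl/fl ES cells and 130.4 ± 8.47 CPM in fl/fl EBd2, but at 13.6 ± 0.401 CPM and 18.7 ± 1.37 CPM in KO. Otx2 and Pou3f1 thus gave little or no sign of the stage in cells labelled KO. T (brachyury), a marker of the primitive streak, stood at 72.1 ± 5.47 CPM in EBd2 labelled KO and at 1.09 CPM or less in the other 3 groups.

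**Figure D1:**
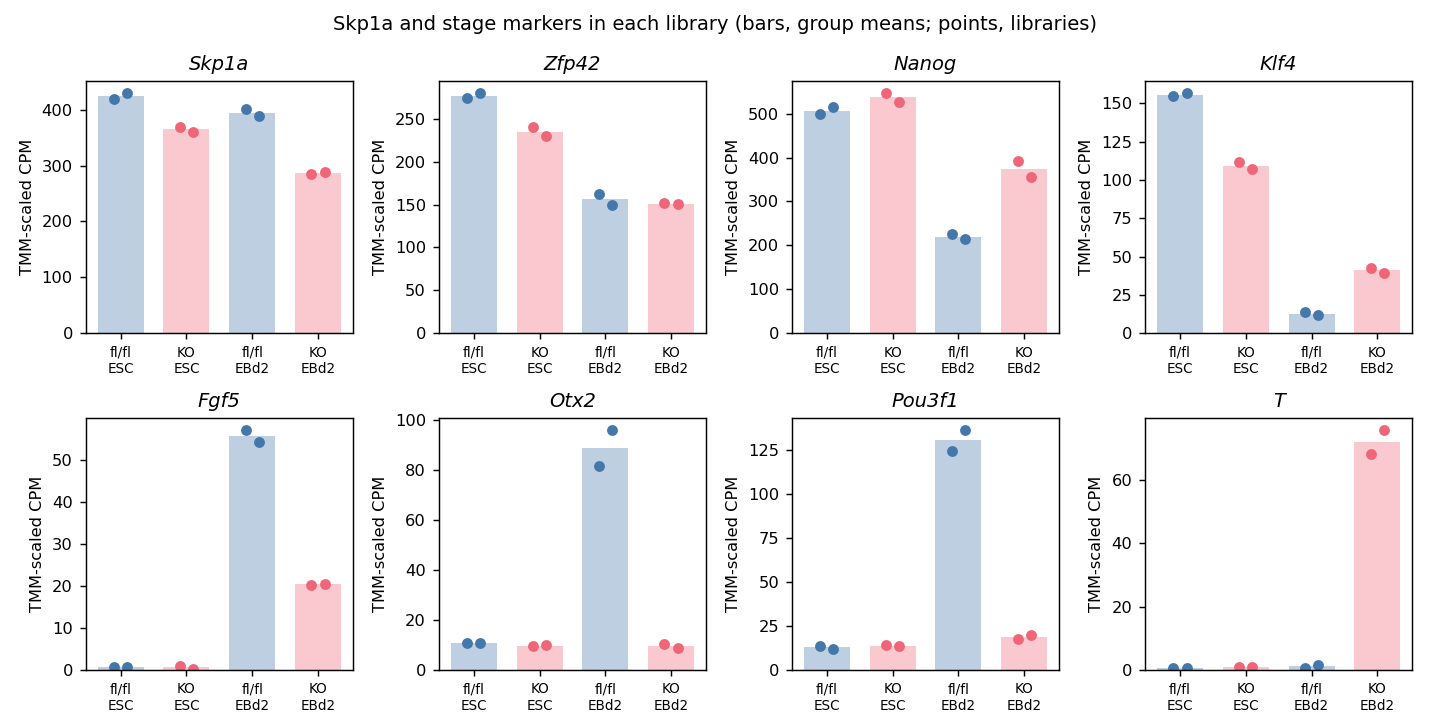
TMM-scaled CPM of Skp1a and 7 stage markers in the 8 libraries, with bars for group means, points for single libraries and axes that start at 0. Skp1a stays between 285.8 and 430.3 CPM in every library, and T lies at 68.19 and 75.93 CPM in the EBd2 libraries labelled KO.

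The first comparison asked how ES cells labelled KO differed from fl/fl ES cells. Most changes were small. Genes of cholesterol synthesis rose and naive and general pluripotency genes fell modestly, but none of the 10 list calls by camera in ES cells held with an estimated correlation between genes. That run has only 4 residual degrees of freedom, so a lost call may reflect low power. Of 29 measured Hox genes 1 was called. Large rises were seen for the surface protein mesothelin, Msln (2.39 ± 0.11, adjusted p = 3.5e-06), the keratin Krt17 (1.65 ± 0.09), the differentiation inhibitor Id2 (1.64 ± 0.06) and the muscle actin Acta1 (1.52 ± 0.10). The clearest falls were in the circadian repressor Cry1 (-0.95 ± 0.05, adjusted p = 3.5e-06), the transporter Slco4a1 (-0.94 ± 0.15), the mitochondrial pyruvate carrier Mpc1 (-0.92 ± 0.15) and the histone demethylase Kdm4b (-0.86 ± 0.05), although Slco4a1 (adjusted p = 0.702) and Mpc1 (0.803) did not pass the test beyond 1.5-fold. Ppp1r3c (-0.91 ± 0.20, adjusted p = 0.00727) and Csnk2a3 (-0.82 ± 0.23, adjusted p = 0.0242) fell as well, but neither call held throughout. That of Ppp1r3c was lost without the fl/fl ES cell library of lot 1 (0.091) or the KO ES cell library of lot 1 (0.0739), after thinning (0.0616) and by DESeq2 (0.0684). That of Csnk2a3 was lost without the fl/fl ES cell library of lot 2 (0.196) or the KO ES cell library of lot 1 (0.149), and by DESeq2 (0.122).

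Of 16542 genes tested, 3926 were called, 1806 higher and 2120 lower, with a median absolute change of 0.28. At least 2-fold changes were seen for 174 genes higher and 31 lower, and a test for changes beyond 1.5-fold called 17 genes in all. Scaling by library size only shifted the median of all genes by 0.07 and gave 2819 genes higher and 1089 lower, so the balance of directions rests on the scaling. The count fell to 2036 without the fl/fl ES cell library of lot 1, 1909 without that of lot 2, 2226 without the KO ES cell library of lot 1 and 2233 without that of lot 12. The 205 genes at least 2-fold changed became 119, 128, 135 and 114 in the same order. With lots as blocks 2236 genes were called, and with libraries thinned to one depth 2080.

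Among 23 cholesterol synthesis genes, 18 rose and 1 fell in ES cells (19 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 2.1e-08, and adjusted p = 0.0888 with an estimated correlation). Examples were farnesyl diphosphate synthase Fdps (0.42 ± 0.03), the sterol dehydrogenase Nsdhl (0.52 ± 0.05) and squalene epoxidase Sqle (0.34 ± 0.04).

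Naive pluripotency genes fell in 10 of 17 cases and rose in 1 (10 and 1 adjusted over the list alone), with a median of -0.21 and camera adjusted p = 0.000474, or adjusted p = 0.288 with an estimated correlation. Klf4 (-0.51 ± 0.04), Esrrb (-0.49 ± 0.04) and Fgf4 (-0.38 ± 0.03) fell, as did Zfp42 (-0.24 ± 0.04, adjusted p = 0.00121). General pluripotency genes included 9 that fell and 0 that rose among 13 (10 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.81e-05, and adjusted p = 0.263 with an estimated correlation). Utf1 (-0.52 ± 0.03) and the RNA-binding protein Lin28a (-0.36 ± 0.03) led these. Nanog (0.08 ± 0.04, adjusted p = 0.199) and Pou5f1 (-0.10 ± 0.03, adjusted p = 0.0685) did not pass, although Nanog passed with library sizes only (adjusted p = 0.0208), and Pou5f1 by DESeq2 (adjusted p = 0.0182) and without pseudogenes and mitochondrial genes (adjusted p = 0.0422).

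Hypoxia and glycolysis genes fell in 16 of 21 cases (median -0.26, camera adjusted p = 7.52e-07, and adjusted p = 0.263 with an estimated correlation; 16 lower and 1 higher adjusted over the list alone). Hexokinase Hk2 (-0.55 ± 0.04), enolase Eno1 (-0.41 ± 0.03) and the mitophagy receptor Bnip3 (-0.54 ± 0.05) were among them. Ribosomal protein genes fell slightly, 38 of 83 (48 adjusted over the list alone), with a median of -0.12 and camera adjusted p = 7.24e-09, or adjusted p = 0.374 with an estimated correlation. With library sizes only, 10 fell and 1 rose, with a median of -0.05, so much of that fall rests on the scaling. Rpl3 (-0.27 ± 0.04) was an example. All 13 mitochondrially encoded transcripts rose (13 adjusted over the list alone; median 0.49, camera adjusted p = 2.86e-07, and adjusted p = 0.263 with an estimated correlation), for example mt-Cytb (0.59 ± 0.08) and mt-Nd2 (0.55 ± 0.06). Replication-dependent histones, whose messages lack a poly(A) tail, fell in 8 of 42 cases (8 adjusted over the list alone) with a median of -0.98. Camera called that list (adjusted p = 7.04e-06), but not with an estimated correlation (adjusted p = 0.0888) nor under the stricter filter on low counts (adjusted p = 0.362).

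Fibroblast feeder markers rose in 10 of 19 cases and fell in 0 (11 and 0 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000186, and adjusted p = 0.263 with an estimated correlation). Tagln (0.69 ± 0.05) and Col6a2 (0.64 ± 0.09) were among them. Trophectoderm genes rose in 6 of 16 cases and fell in 1 (7 and 2 adjusted over the list alone), led by the keratins Krt8 (0.63 ± 0.04) and Krt18 (0.52 ± 0.04). Their median was 0.44 (camera adjusted p = 0.0163, and adjusted p = 0.263 with an estimated correlation). That call was lost without the fl/fl ES cell library of lot 2 (adjusted p = 0.0548), with lots as blocks (0.101) and after thinning (0.124).

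Transcripts of PRC2 subunits moved little in ES cells. Of 12 subunits 4 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.07. Ezh1 was lower (-0.27 ± 0.04, adjusted p = 0.00134), as was Suz12 (-0.13 ± 0.03, adjusted p = 0.00997), while Ezh2 (-0.07 ± 0.04, adjusted p = 0.176), Jarid2 (-0.07 ± 0.04, adjusted p = 0.154) and Eed (-0.13 ± 0.04, adjusted p = 0.0508) did not pass. The Suz12 call was lost without the fl/fl ES cell library of lot 1 (0.0593), that of lot 2 (0.0863) or the KO ES cell library of lot 1 (0.1), with lots as blocks (0.0643), after thinning (0.0606) and with library sizes only (0.159). Eed passed without the KO ES cell library of lot 1 (0.0397), the KO EBd2 library of lot 1 (0.0416) or that of lot 2 (0.042), with RLE scaling (0.0356), with no filter on low counts (0.0119), without pseudogenes and mitochondrial genes (0.0269), in a fit of the 4 ES cell libraries (0.0403) and by DESeq2 (0.0367). The PRC2 list call (camera adjusted p = 0.0493, and adjusted p = 0.263 with an estimated correlation) was lost without the fl/fl ES cell library of lot 1 (0.0629) or lot 2 (0.0922), the KO ES cell library of lot 1 (0.0691) or lot 12 (0.072), and the KO EBd2 library of lot 1 (0.058) or lot 2 (0.0578). It was also lost with library sizes only (0.219, with 2 lower), under the stricter filter (0.132), with lots as blocks (0.0616), with lot 1 against the others as a block (0.0611), without pseudogenes and mitochondrial genes (0.0603), after thinning (0.0532) and in a fit of the 4 ES cell libraries (0.0809).

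The Hox list had 1 gene higher of 29 in ES cells (0 adjusted over the list alone), with a median of 0.04 and camera adjusted p = 0.501. Of 26 PRC1 subunits 3 rose and 9 fell (5 and 11 adjusted over the list alone), among them Phc1 (-0.45 ± 0.03), and the median of -0.07 became 0.00, with 5 higher and 6 lower, with library sizes only (camera adjusted p = 0.116). The PRC1 protein Kdm2b stood at 0.06 ± 0.04 (adjusted p = 0.34). The PRC1 subunit Pcgf1 fell (-0.33 ± 0.09, adjusted p = 0.0218), a call lost without the fl/fl ES cell library of lot 1 (0.106) or lot 2 (0.113), without the KO ES cell library of lot 1 (0.0739) or lot 12 (0.113), with lots as blocks (0.233), after thinning (0.263), by DESeq2 (0.173) and with library sizes only (0.0601). Cdkn1a rose slightly (0.15 ± 0.04, adjusted p = 0.0134), a call lost without the fl/fl ES cell library of lot 1 (0.0828) or lot 2 (0.0771), the KO ES cell library of lot 1 (0.0564) or lot 12 (0.0689), with lots as blocks (0.105), after thinning (0.692) and by DESeq2 (0.0808).

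Cyclin E transcripts rose, Ccne1 by 0.62 ± 0.03 and Ccne2 by 1.01 ± 0.07, and so did the F-box gene Skp2 (0.44 ± 0.04), while the cell cycle inhibitor Cdkn1b fell (-0.41 ± 0.05, adjusted p = 0.000202). Among 25 G1/S and E2F targets 9 rose and 7 fell (10 and 8 adjusted over the list alone; median 0.07, camera adjusted p = 0.284), and with library sizes only 14 rose and 5 fell, with a median of 0.14. T (0.78 ± 0.35, adjusted p = 0.138), Otx2 (-0.15 ± 0.11, 0.371), Gata6 (-0.13 ± 0.11, 0.495) and Fgf5 (0.13 ± 0.43, 0.859) did not pass.

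The second comparison asked the same of EBd2. Embryoid bodies labelled KO carried higher levels of Hox, two-cell-like and germline genes than fl/fl embryoid bodies, and lower levels of cholesterol synthesis genes. These 4 of 18 list calls held with an estimated correlation, but only just. They share a camera adjusted p of 0.049, set by the two-cell-like p of 0.00653, so they stand or fall together. Much of the two-cell-like list consists of gene families whose copies may share reads, which leaves that p uncertain. Endoderm genes, Wnt targets and feeder markers were higher as well, and epiblast and ribosomal protein genes lower. These list calls did not hold with an estimated correlation, where endoderm had a camera p of 0.0118 (adjusted p = 0.0708). T rose by 6.0 ± 0.19 (adjusted p = 5.82e-10) and Hoxb9 by 5.09 ± 0.30 (adjusted p = 6.11e-08), while Otx2 changed by -3.23 ± 0.11 (adjusted p = 8.52e-10) and the DNA methyltransferase Dnmt3b by -2.45 ± 0.05 (adjusted p = 2.65e-11).

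By fitted log2 fold change, which is uncertain against 0 counts, the largest rises were of genes nearly silent in fl/fl EBd2. The lower bounds given here do not rank these genes against those with measured rises, such as T. Msln had 629 counts in KO and 0 in fl/fl and was at least 158-fold higher. Sprr2a3, a cornified envelope gene (at least 37.1-fold), the keratinocyte gene Krtdap (at least 29.6-fold) and the channel subunit Cnga4 (at least 28.8-fold) also had 0 counts in fl/fl. The Wnt target Sp5 had 1287 counts against 2, a ratio of 484 with a 95% counting interval of 134 to 4000. Sprr2a2 had 1879 against 3, a ratio of 471 with an interval of 161 to 2290, and possible sharing of reads among Sprr2a copies leaves both Sprr2a values uncertain. Falls were led by carbonic anhydrase Car14 (-4.20 ± 0.27) and the transcription factors Bcl11a (-4.14 ± 0.22) and Insm1 (-3.65 ± 0.23). The cannabinoid receptor Cnr1 (-3.43 ± 0.24), the epiblast factor Zic2 (-3.32 ± 0.11) and the channel regulator Clca4a (-3.31 ± 0.27) followed.

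In all, 10289 genes were called, 5072 higher and 5217 lower, with a median absolute change of 0.69. At least 2-fold changes numbered 2463 higher and 1021 lower. Scaling by library size only shifted the median of all genes by 0.23 and gave 7075 higher and 3345 lower. A test for changes beyond 1.5-fold called 3910 genes. The at least 2-fold changes numbered 3484 in all, and 2014 in a separate fit under the stricter filter, which tests fewer genes.

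Of 29 measured Hox genes, 27 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 2.97, or 2.95 with members at 0 counts set at their bound. Hoxa11 (3.75 ± 0.37) was an example, and Hoxc10, with 81 counts against 0, was at least 20.3-fold higher. Many Hox genes had few counts in fl/fl EBd2, so their folds are uncertain. The gap joins a fall from ES cells in fl/fl (median -1.85) with a rise in KO (1.10). Hoxb9, for example, had 142 counts in fl/fl ES cells and 5 in fl/fl EBd2, against 214 and 232 in KO. The list call (camera adjusted p = 9.18e-07) held with an estimated correlation (adjusted p = 0.049). Other developmental regulators held by Polycomb rose in 16 of 34 cases and fell in 3 (15 and 3 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 0.00223, adjusted p = 0.11 with an estimated correlation, and adjusted p = 0.278 under the stricter filter). The cell cycle inhibitor Cdkn2a (1.38 ± 0.10) and the ligand Wnt6 (4.02 ± 0.35) rose. Of 12 PRC2 subunits 6 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.17, camera adjusted p = 0.52). With library sizes only 9 rose and 1 fell, with a median of 0.40, so their balance rests on the scaling.

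Single PRC2 genes moved by less than 2-fold in EBd2. Ezh2 (0.23 ± 0.04, adjusted p = 0.00071), Eed (0.29 ± 0.06, 0.000794) and Epop (0.68 ± 0.05) rose, while Ezh1 (-0.87 ± 0.07) fell. Jarid2 was lower (-0.15 ± 0.04, adjusted p = 0.00479) but higher, and not called, with library sizes only (0.08, adjusted p = 0.0832). Suz12 did not pass (-0.08 ± 0.03, adjusted p = 0.0671) and was called higher with library sizes only (0.15, adjusted p = 0.00256). PRC1 subunits split, with 7 higher and 13 lower of 26 (7 and 13 adjusted over the list alone), and their median of -0.20 became 0.03, with 13 higher and 9 lower, with library sizes only (camera adjusted p = 0.267). Phc1 (-1.31 ± 0.03) and Kdm2b (-0.73 ± 0.05) fell. Pcgf1 fell too (-0.57 ± 0.15, adjusted p = 0.00758), but not without the fl/fl EBd2 library of lot 1 (0.0529) or the KO EBd2 library of lot 1 (0.0751), nor with library sizes only (0.113). Among 23 SCF partners of SKP1, 14 fell and 4 rose (14 and 4 adjusted over the list alone; median -0.28, camera adjusted p = 0.0378, and adjusted p = 0.133 with an estimated correlation), with Skp2 higher (0.92 ± 0.05). That call was lost without the fl/fl EBd2 library of lot 12 (adjusted p = 0.0504), with library sizes only (0.151, with 5 higher and 7 lower), under the stricter filter (0.137), after thinning (0.0591) and in a fit of the 4 EBd2 libraries (0.0595).

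Endoderm, streak and mesoderm genes were more often higher than lower in EBd2 labelled KO, with list calls that did not hold with an estimated correlation. Of 19 primitive and visceral endoderm genes 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.85 (camera adjusted p = 5.86e-08, and adjusted p = 0.0708 with an estimated correlation). The basement membrane genes Col4a1 (2.40 ± 0.03) and Sparc (1.89 ± 0.04) and the transcription factor Gata6 (2.52 ± 0.10) were among them. Primitive streak and mesendoderm genes rose in 8 of 13 cases and fell in 0 (9 and 0 adjusted over the list alone; median 1.36, camera adjusted p = 0.0106, and adjusted p = 0.11 with an estimated correlation), including Eomes (2.08 ± 0.11) and Nodal (1.29 ± 0.05). Mesoderm genes rose in 10 of 17 cases and fell in 1 (10 and 1 adjusted over the list alone; median 1.34, camera adjusted p = 0.0125, and adjusted p = 0.162 with an estimated correlation), including Bmp4 (2.43 ± 0.15). With library sizes only, the streak call (adjusted p = 0.0618) and the mesoderm call (adjusted p = 0.0528) were lost.

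Trophectoderm genes rose in 11 of 16 cases and fell in 2 (11 and 2 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 0.000559, and adjusted p = 0.11 with an estimated correlation). Krt8 (2.26 ± 0.04) and the X-linked homeobox gene Rhox6 (2.43 ± 0.09, with reads possibly shared among Rhox copies) were examples. Of 16 Wnt targets 14 rose and 1 fell (14 and 1 adjusted over the list alone; median 1.64, camera adjusted p = 8.55e-05, and adjusted p = 0.0874 with an estimated correlation), with Dkk1 (4.41 ± 0.14) and Axin2 (2.58 ± 0.09) beside Sp5 and T. Neuroectoderm genes went both ways, 7 higher and 6 lower of 18 (7 and 6 adjusted over the list alone; median 0.34, camera adjusted p = 0.52), such as Gbx2 (2.45 ± 0.11) and Msi1 (-2.16 ± 0.11).

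All 17 two-cell-like genes rose (17 adjusted over the list alone), with a median of 2.82, or 2.79 with members at their bound. Zscan4d (3.31 ± 0.30) and Zscan4f (2.92 ± 0.16) were examples. Much of the list consists of families of copies (Zscan4, Usp17l, Tcstv and Tdpoz) among which reads are possibly shared. The 17 members may therefore not be 17 separate measurements. Of 23 germline genes 19 rose and 2 fell (19 and 2 adjusted over the list alone; median 1.55), among them Tex11 (3.84 ± 0.14) and the Piwi gene Piwil2 (2.21 ± 0.08). Both calls (camera adjusted p = 6.06e-06 for two-cell-like and 3.94e-06 for germline genes) held with an estimated correlation (adjusted p = 0.049 for each).

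Formative and primed epiblast genes fell in 11 of 14 cases and rose in 2 (11 and 2 adjusted over the list alone; median -1.72, camera adjusted p = 0.000521, and adjusted p = 0.11 with an estimated correlation). Fgf5 fell by 1.45 (SE 0.12, adjusted p = 9.59e-07). Naive pluripotency genes rose in 9 of 17 cases and fell in 5 (9 and 6 adjusted over the list alone; median 0.76, camera adjusted p = 0.169), with Tbx3 (2.31 ± 0.05), Spp1 (1.96 ± 0.05) and Nanog (0.76 ± 0.05) higher and Fgf4 (-0.73 ± 0.04) lower. Zfp42 did not pass (-0.04 ± 0.05, adjusted p = 0.442) but was called higher with library sizes only (0.18, adjusted p = 0.00441). General pluripotency genes had 4 higher and 7 lower of 13 (4 and 7 adjusted over the list alone; median -0.52, camera adjusted p = 0.0607), with falls in Lin28a (-1.79 ± 0.03), Utf1 (-1.58 ± 0.04) and Pou5f1 (-0.53 ± 0.04). That list passed without the fl/fl EBd2 library of lot 1 (adjusted p = 0.0473) or the KO EBd2 library of lot 1 (0.047), and with no filter on low counts (0.0146).

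Cholesterol synthesis genes, higher in ES cells labelled KO, were lower in EBd2 labelled KO. Of 23, 22 fell and 1 rose (22 and 1 adjusted over the list alone; median -1.08), including lanosterol synthase Lss (-2.12 ± 0.05), Fdps (-1.84 ± 0.04) and Sqle (-1.44 ± 0.04). The call (camera adjusted p = 7.98e-09) held with an estimated correlation (adjusted p = 0.049). Ribosomal protein genes fell in 79 of 83 cases and rose in 1 (79 and 1 adjusted over the list alone; median -0.74, camera adjusted p = 1.6e-17, and adjusted p = 0.213 with an estimated correlation), including Rps26 (-1.17 ± 0.04) and Rpl3 (-1.04 ± 0.04).

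In EBd2, G2/M genes rose in 20 of 24 cases and fell in 1 (20 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 1.49e-05, and adjusted p = 0.0874 with an estimated correlation), for example the spindle protein Nusap1 (1.02 ± 0.04). Of 25 G1/S and E2F targets 11 rose and 11 fell (12 and 12 adjusted over the list alone). Their median of -0.09 had the sign of the test (camera adjusted p = 0.707), their mean of 0.01 had the opposite sign, and the median became 0.14, with 13 higher and 9 lower, with library sizes only. Ccne2 (2.15 ± 0.07) and Ccne1 (0.94 ± 0.04) rose and Cdkn1b fell (-1.04 ± 0.07). Targets of p53 rose in 14 of 24 cases and fell in 5 (14 and 6 adjusted over the list alone; median 0.42, camera adjusted p = 0.0125, and adjusted p = 0.281 with an estimated correlation), including Perp (2.97 ± 0.07) and the cell cycle inhibitor Cdkn1a (1.18 ± 0.04).

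The stress, NRF2, NF-kappaB, interferon and imprinted lists were not called by camera in EBd2. Integrated stress and unfolded protein response genes had 4 higher and 9 lower of 22 (4 and 9 adjusted over the list alone; median -0.20, camera adjusted p = 0.172), with Atf3 higher (3.07 ± 0.16) and Atf4 lower (-1.31 ± 0.05), and their median became 0.03, with 8 higher and 4 lower, with library sizes only. NRF2 targets had 5 higher and 7 lower of 15 (6 and 7 adjusted over the list alone), such as Hmox1 (0.83 ± 0.05) and Gclm (-1.23 ± 0.04). Their median of 0.07 was opposite in sign to their mean of -0.07 and to the test (camera adjusted p = 0.52), and became 0.30 with library sizes only. NF-kappaB targets had 6 higher and 1 lower of 13 (6 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 0.267), among them Bcl3 (1.87 ± 0.15). Interferon response genes had 5 higher and 2 lower of 13 (5 and 2 adjusted over the list alone; median 0.62, camera adjusted p = 0.15). Imprinted genes had 10 higher and 5 lower of 16 (10 and 5 adjusted over the list alone; median 0.30, camera adjusted p = 0.354), with Igf2 (2.44 ± 0.05) higher and Snrpn (-1.50 ± 0.05) lower.

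Calls of the hypoxia and histone lists in EBd2 were unstable. Hypoxia and glycolysis genes had 6 higher and 12 lower of 21 (6 and 12 adjusted over the list alone; median -0.69, camera adjusted p = 0.044, and adjusted p = 0.491 with an estimated correlation), including Eno1 (-1.32 ± 0.04) and Bnip3 (-1.72 ± 0.08). That call was lost without the fl/fl ES cell library of lot 1 (0.0508) or lot 2 (0.0519), the KO ES cell library of lot 1 (0.0504) or lot 12 (0.0519), the fl/fl EBd2 library of lot 12 (0.0504) or the KO EBd2 library of lot 2 (0.0615). It was also lost under the stricter filter (0.0542), with lots as blocks (0.09), with lot 1 against the others as a block (0.0519) and in a fit of the 4 EBd2 libraries (0.0655). Histones had 4 higher and 15 lower of 42 (4 and 10 adjusted over the list alone; median -1.20, or -1.05 with members at their bound, camera adjusted p = 0.0486, and adjusted p = 0.133 with an estimated correlation). Their call was lost without the fl/fl ES cell library of lot 2 (0.0652), the fl/fl EBd2 library of lot 1 (0.0948) or lot 12 (0.0504) or the KO EBd2 library of lot 2 (0.0606) and after thinning (0.0836), and their median turned to 0.27 under the stricter filter (0.96). Mitochondrially encoded transcripts had 8 higher and 0 lower of 13 (8 and 0 adjusted over the list alone; median 0.23, camera adjusted p = 0.167), and were called without the fl/fl EBd2 library of lot 1 (0.00871).

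Markers of fibroblast feeder cells moved with these groups. Of 19, 17 were higher and 0 lower in EBd2 labelled KO (17 and 0 adjusted over the list alone; median 1.93, camera adjusted p = 3.94e-06, and adjusted p = 0.0874 with an estimated correlation), such as the collagens Col6a1 (3.59 ± 0.14) and Col1a2 (2.75 ± 0.15). In fl/fl EBd2 13 of the 19 reached 1 CPM, and in fl/fl ES cells 18 did. The fry test, which does not compare lists with other genes, called 28 of 30 lists in EBd2 and 21 of 30 in ES cells.

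**Figure D2:**
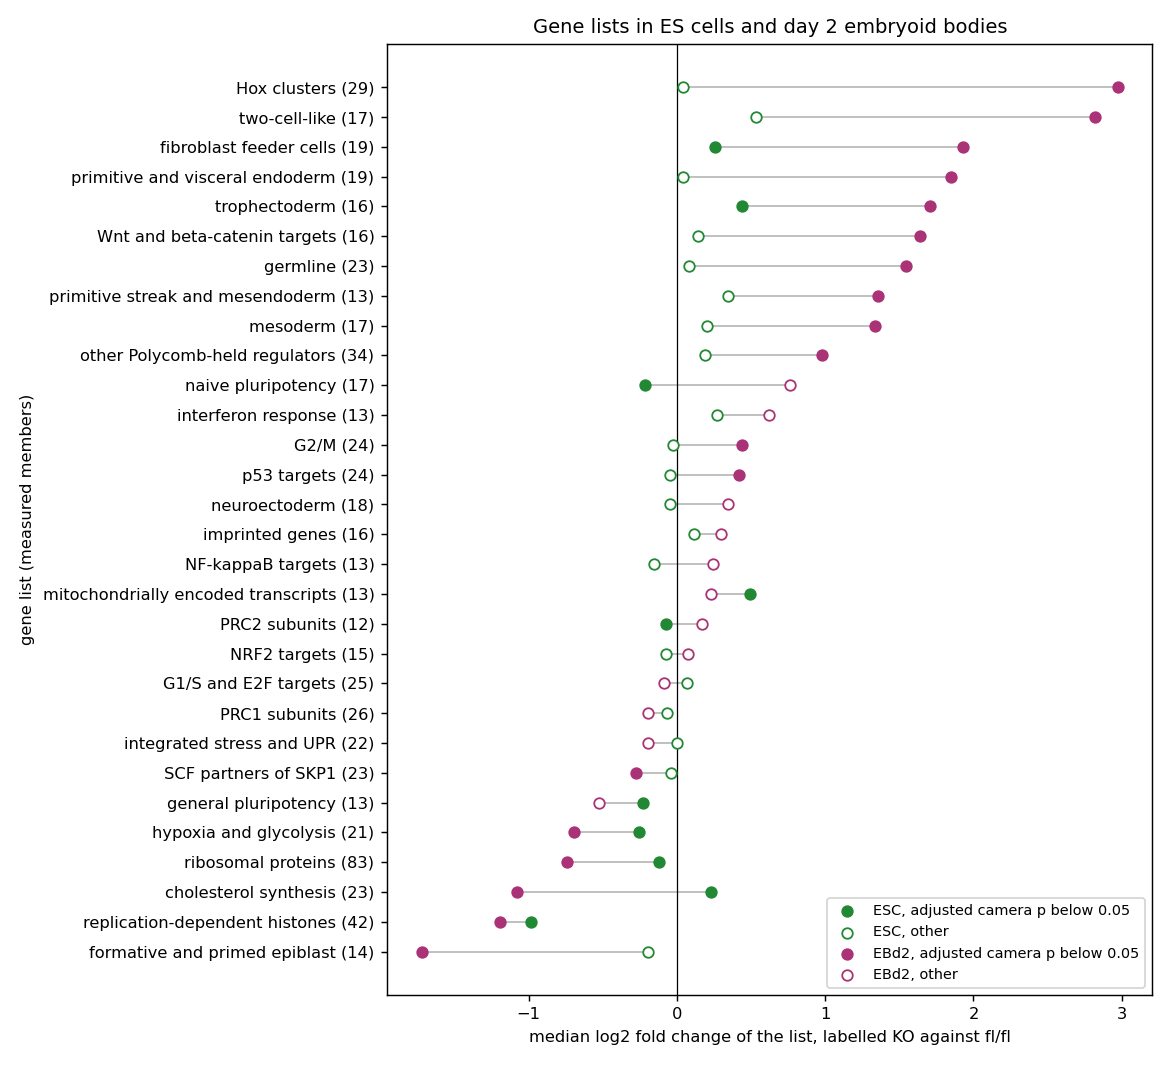
Median log2 fold change of each of the 30 gene lists, labelled KO against fl/fl, in ES cells (green) and EBd2 (purple), with filled points where the adjusted camera p at a preset correlation of 0.01 is below 0.05. The Hox median lies at 0.04 in ES cells and 2.97 in EBd2, and cholesterol synthesis lies at 0.23 and -1.08. With library sizes only, the medians of neuroectoderm, PRC1, SCF partners, p53 targets and G2/M in ES cells and of PRC1, G1/S and the stress list in EBd2 change sign.

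**Figure D3:**
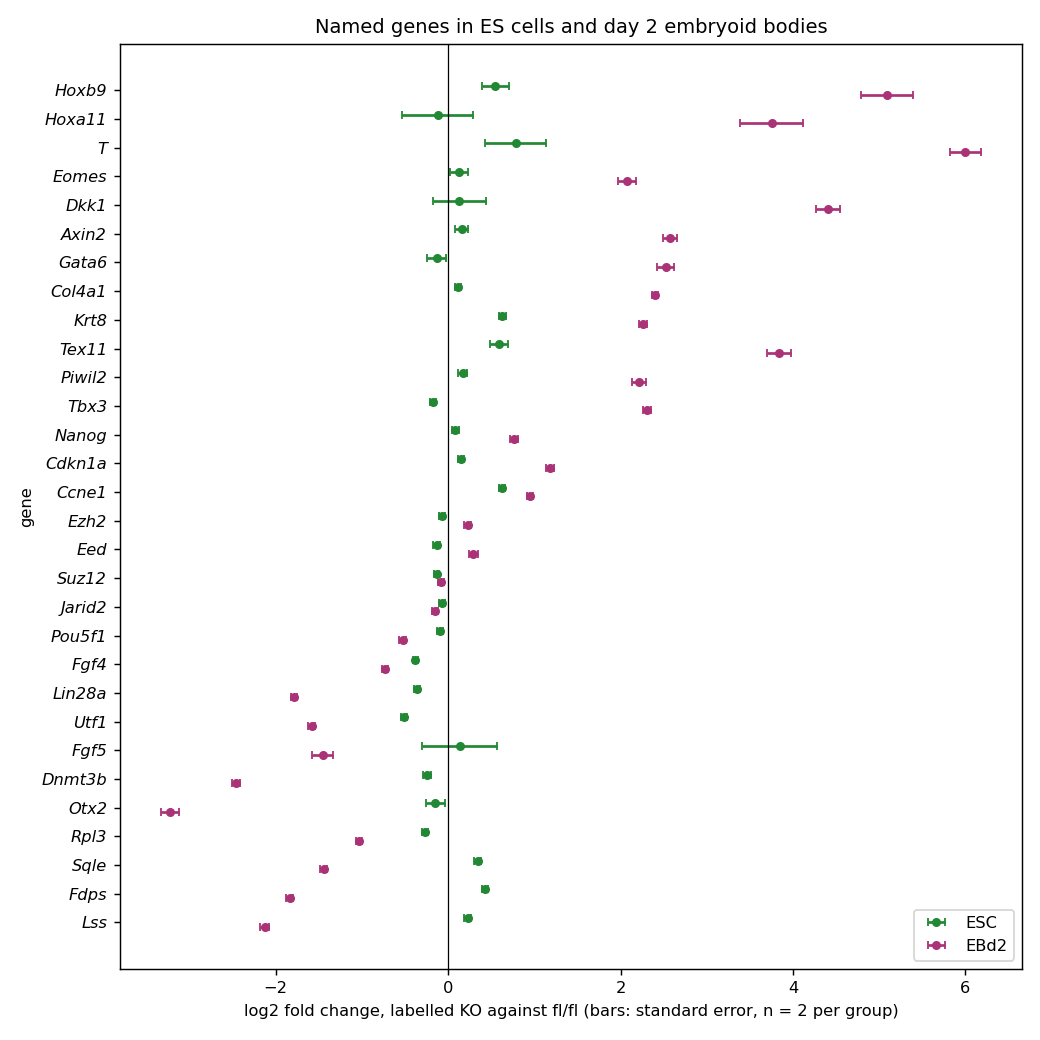
Log2 fold changes, labelled KO against fl/fl, of 30 genes in ES cells (green) and EBd2 (purple), with bars for the standard error derived from the F statistic (n = 2 per group). T lies at 0.78 in ES cells and 6.0 in EBd2, and Fdps at 0.42 and -1.84. Suz12 and Jarid2 in EBd2 turn positive with library sizes only.

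The third comparison gave the differentiation response of fl/fl cells. From ES cells to EBd2, naive pluripotency genes fell and epiblast genes rose, and feeder markers were sharply lower, although none of the 14 lists called in fl/fl held with an estimated correlation. Apolipoprotein Apob (7.01 ± 0.13, adjusted p = 2.19e-11) and Fgf5 (6.67 ± 0.19) rose most, followed by transthyretin Ttr (5.64 ± 0.39), the mucin Muc13 (5.48 ± 0.37), Bcl11a (4.84 ± 0.21) and Vrtn (4.66 ± 0.13). The largest falls were of mesenchymal genes, among them the feeder markers Lox and Acta2. Whether they reflect regulation in ES cells or fewer fibroblasts in EBd2 was not tested. Cavin2 had 281 counts in ES cells and 0 in EBd2 and was at least 35.2-fold lower, and Col8a1 was lower by a ratio of 146 with a counting interval of 49.7 to 707. Col12a1 (-6.89 ± 0.19), the lysyl oxidase Lox (-6.81 ± 0.18), smooth muscle actin Acta2 (-6.60 ± 0.18) and caveolin Cav1 (-6.46 ± 0.25) followed. Skp1a was slightly lower (-0.11 ± 0.03, adjusted p = 0.0178), a call lost without the fl/fl ES cell library of lot 2 (0.0889), without the fl/fl EBd2 library of lot 12 (0.0922) and with lots as blocks (0.158).

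In fl/fl cells 9763 genes were called, 4777 higher and 4986 lower, and 1235 rose and 1570 fell at least 2-fold. A test for changes beyond 1.5-fold called 3043. The at least 2-fold changes numbered 2805 in all, and 1597 in a separate fit under the stricter filter. All 14 formative and primed epiblast genes rose (14 adjusted over the list alone; median 2.86, camera adjusted p = 3e-08, and adjusted p = 0.067 with an estimated correlation), including Dnmt3b (3.03 ± 0.05), Pou3f1 (3.35 ± 0.08) and Otx2 (3.06 ± 0.09). Naive pluripotency genes fell in 15 of 17 cases and rose in 1 (15 and 1 adjusted over the list alone; median -1.19, camera adjusted p = 3.67e-07, and adjusted p = 0.131 with an estimated correlation), including Klf4 (-3.63 ± 0.07), Tfcp2l1 (-2.47 ± 0.07) and Nanog (-1.21 ± 0.05). Zfp42 fell as well (-0.83 ± 0.04), while Pou5f1 did not pass (-0.06 ± 0.04, adjusted p = 0.16) except with no filter on low counts (0.0473). Of 19 feeder markers 15 fell and 1 rose (15 and 1 adjusted over the list alone; median -2.99, camera adjusted p = 3.49e-07, and adjusted p = 0.067 with an estimated correlation), such as Col1a1 (-4.87 ± 0.12).

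Hox genes were lower in fl/fl EBd2 than in fl/fl ES cells, 14 of 29 called lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -1.85, or -1.76 with members at their bound. Hoxb9 (-3.39 ± 0.36) was an example, and fewer fibroblasts in EBd2 were not tested as a source of these falls. Camera called the list (adjusted p = 0.000533), but not with an estimated correlation (adjusted p = 0.067), under the stricter filter (0.218) or in a fit of the 4 fl/fl libraries (0.0539). PRC2 subunits fell in 9 of 12 cases and rose in 2 (9 and 2 adjusted over the list alone; median -0.42, camera adjusted p = 0.0164, and adjusted p = 0.131 with an estimated correlation), including Suz12 (-0.53 ± 0.03), Ezh2 (-0.49 ± 0.04) and Eed (-0.51 ± 0.05). Kdm2b rose (1.04 ± 0.05). T (1.04 ± 0.44, adjusted p = 0.0631) did not pass, but did without the fl/fl ES cell library of lot 2 (0.0401) or the fl/fl EBd2 library of lot 1 (0.0259) and with lot 1 against the others as a block (0.0475).

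The fourth comparison gave the same response in cells labelled KO. Epiblast induction was smaller (median interaction -1.83, camera adjusted p = 0.000104, and adjusted p = 0.0983 with an estimated correlation). Endoderm genes, which also rose in fl/fl, and Wnt targets rose. In fl/fl, 8 of 16 Wnt targets rose and 3 fell (8 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 0.449). None of the 19 lists called in cells labelled KO held with an estimated correlation. Apob (7.79 ± 0.10, adjusted p = 1.1e-12), Ttr (7.46 ± 0.28), Sprr2a2 (7.25 ± 0.16, with reads possibly shared among copies), the aquaporin Aqp8 (7.12 ± 0.26), Spink1 (7.01 ± 0.16) and the homeobox gene Nkx1-2 (6.75 ± 0.30) rose most. Ankrd1 was lower by a ratio of 61.2 (counting interval 16.8 to 508, 252 counts against 2). Cavin2 (-5.47 ± 0.29), Acta2 (-5.30 ± 0.13), Col8a1 (-5.01 ± 0.15), Acta1 (-4.74 ± 0.18) and Lox (-4.14 ± 0.11) fell. Acta2 and Lox are feeder markers, and fewer fibroblasts in EBd2 were not tested as a source here either. Skp1a fell by 0.34 (SE 0.03, adjusted p = 3.86e-06).

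In cells labelled KO 10721 genes were called, 5248 higher and 5473 lower, and 1918 rose and 1327 fell at least 2-fold. Library sizes alone shifted the median of all genes by 0.15 and gave 6665 higher and 4106 lower, and a test beyond 1.5-fold called 3733. The at least 2-fold changes numbered 3245 in all, and 1704 in a separate fit under the stricter filter. All 19 primitive and visceral endoderm genes rose (19 adjusted over the list alone; median 2.93, camera adjusted p = 1.92e-12, and adjusted p = 0.0903 with an estimated correlation), including Dab2 (3.73 ± 0.04) and Col4a1 (2.86 ± 0.03), and Gata6 rose by 2.97 ± 0.09. In fl/fl cells 12 of the 19 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.78, camera adjusted p = 0.000401, and adjusted p = 0.131 with an estimated correlation). Of 16 Wnt targets 15 rose and 0 fell (15 and 0 adjusted over the list alone; median 2.23, camera adjusted p = 4.1e-06, and adjusted p = 0.0974 with an estimated correlation), including Dkk1 (6.24 ± 0.14), T (6.26 ± 0.15) and Sp5 (4.68 ± 0.10). Formative and primed epiblast genes rose in 12 of 14 cases and fell in 1 (12 and 1 adjusted over the list alone; median 0.91, camera adjusted p = 0.00109, and adjusted p = 0.16 with an estimated correlation), with Fgf5 at 5.08 ± 0.22 and Dnmt3b at 0.82 ± 0.05, while Otx2 did not pass (-0.02 ± 0.13, adjusted p = 0.897). Klf4 (-1.42 ± 0.05) and Nanog (-0.53 ± 0.05) fell. Ezh2 fell slightly (-0.19 ± 0.04, adjusted p = 0.00122), but not with library sizes only (-0.04, adjusted p = 0.384). Eed did not pass (-0.08 ± 0.05, adjusted p = 0.149), but did without the KO ES cell library of lot 12 (0.0405), with no filter on low counts (0.0196) and with lots as blocks (0.0175).

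Hox genes rose from ES cells to EBd2 in cells labelled KO, 15 of 29 called higher and 0 lower (15 and 0 adjusted over the list alone; median 1.10, camera adjusted p = 0.00734, and adjusted p = 0.16 with an estimated correlation), including Hoxa11 (4.11 ± 0.31). Two-cell-like genes all rose, 17 of 17 (17 adjusted over the list alone; median 2.70, camera adjusted p = 4.1e-06, and adjusted p = 0.0903 with an estimated correlation), including Zscan4f (2.39 ± 0.12), with reads possibly shared among copies. Feeder markers fell in 12 of 19 cases and rose in 1 (12 and 1 adjusted over the list alone; median -1.28, camera adjusted p = 0.00247, and adjusted p = 0.162 with an estimated correlation). Cholesterol synthesis genes, of which 18 of 23 rose in fl/fl cells (18 adjusted over the list alone; median 0.46, camera adjusted p = 1.7e-05, and adjusted p = 0.067 with an estimated correlation), fell here in 19 of 23 cases. Their median in cells labelled KO was -0.71 (19 lower and 3 higher adjusted over the list alone; camera adjusted p = 2.36e-06, and adjusted p = 0.0974 with an estimated correlation), with Fdps at -1.26 ± 0.04 against 1.01 ± 0.03 in fl/fl.

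**Figure D4:**
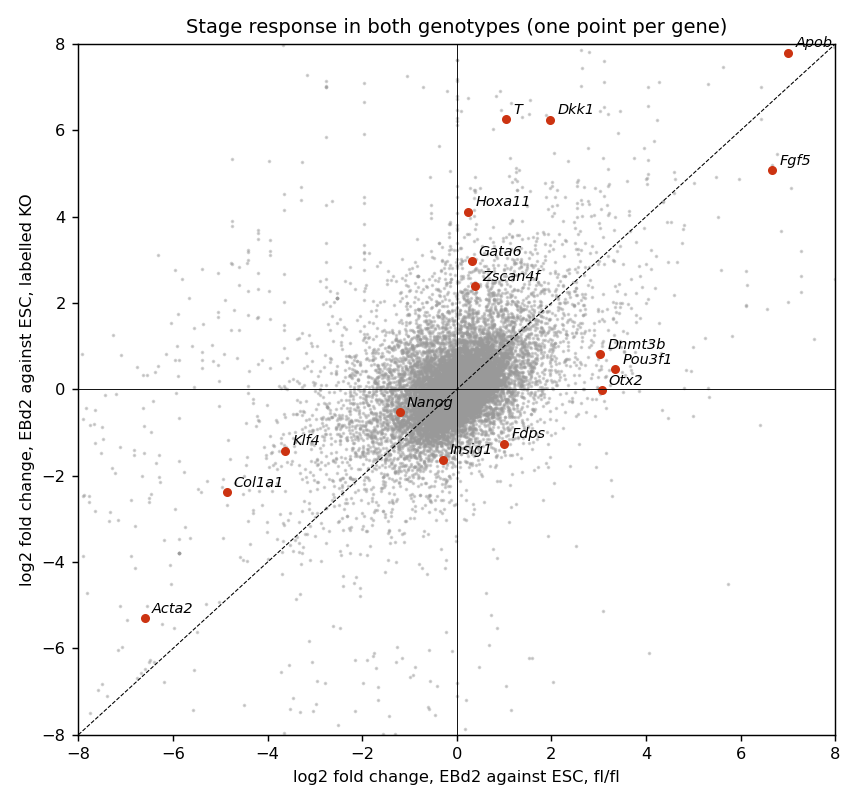
Log2 fold change from ES cells to EBd2 in fl/fl (horizontal axis) against that in cells labelled KO (vertical axis), with 1 point per gene, named genes in red and the dashed line marking equal change. Of the 16542 genes tested 61 lie outside the axes. Otx2 lies at 3.06 in fl/fl and -0.02 in KO, and Fdps at 1.01 and -1.26.

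The interaction asked directly whether the genotype effect differed between stages. It was called for 7948 genes, 3704 with a more positive and 4244 with a more negative effect in EBd2, and for 1615 and 877 genes by at least 2-fold. With library sizes only, the median of all genes shifted by 0.16 and the split was 5008 to 2992, and a test beyond 1.5-fold called 2331 genes. T (5.22 ± 0.53, adjusted p = 1.05e-05), Gata6 (2.65 ± 0.15), Tbx3 (2.48 ± 0.06), Col4a1 (2.28 ± 0.05) and Cdkn1a (1.03 ± 0.06) had the more positive effect in EBd2. Otx2 (-3.08 ± 0.16), Fdps (-2.26 ± 0.05), Dnmt3b (-2.21 ± 0.06) and Kdm2b (-0.79 ± 0.06) had the more negative effect. The Hox list (20 more positive and 0 more negative of 29, 22 and 0 adjusted over the list alone; median 3.02, or 2.92 with members at their bound) and the cholesterol list (1 and 22 of 23, 1 and 22 adjusted over the list alone; median -1.23) were called (camera adjusted p = 6.65e-07 and 2.25e-12), and both held with an estimated correlation (adjusted p = 0.0423). The Skp1a effect was more negative in EBd2 (-0.24 ± 0.05, adjusted p = 0.00159), but not with library sizes only (-0.08, adjusted p = 0.171).

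Genotype effects in ES cells and EBd2 were compared across genes, which are not independent replicates. Pearson's r was 0.278 and Spearman's rho 0.386 over 16542 genes, from separate libraries. Of 3177 genes called at both stages, 2688 (84.6%) changed in the same direction and 489 in opposite directions. Both higher were 1163, against 553.7 if calls were independent (one-sided Fisher's exact p = 2.15e-217), and both lower were 1525, against 668.6. The correlation became 0.0405 with lots as blocks, 0.379 under the stricter filter and 0.402 when each stage was fitted alone.

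Stage responses of fl/fl and KO cells correlated at r = 0.443 and rho = 0.439 across genes. Of 7147 genes called in both, 5545 (77.6%) changed in the same direction. Among the 2805 genes changed at least 2-fold in fl/fl, 1694 were called in the same direction in KO. A further 277 were called in the opposite direction and 834 were not called. The median ratio of the KO to the fl/fl change over these 2805 genes was 0.464. Over the 3245 genes changed at least 2-fold in KO, the median ratio of the fl/fl to the KO change was 0.454. Both ratios cover genes selected for a large change in the genotype used as divisor. The value of 0.464 therefore does not show a weaker response in KO. The correlation became 0.303 with lots as blocks. Feeder markers fell in both genotypes, and their part in the correlation was not tested.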

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

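The interaction was planned before the data were examined, while the tests that weigh explanations here were chosen after the results had been seen. The genotype effect differed between ES cells and EBd2 for 7948 genes by the interaction term of edgeR's quasi-likelihood model. Among lists, the camera test called a more positive effect in EBd2 for naive pluripotency (median interaction 0.68), streak and mesendoderm (1.20), mesoderm (1.08), primitive and visceral endoderm (1.81), trophectoderm (1.24), two-cell-like (2.53), germline (1.51) and Hox genes (3.02). The same was called for other regulators held by Polycomb (0.88), p53 targets (0.54), Wnt targets (1.5), G2/M genes (0.46) and feeder markers (1.71). A more negative effect was called for formative and primed epiblast genes (-1.83), cholesterol synthesis (-1.23) and ribosomal proteins (-0.62). With an estimated correlation, 5 of these 16 calls held: primitive and visceral endoderm and two-cell-like (adjusted p = 0.0475 each), and germline, Hox and cholesterol (adjusted p = 0.0423 each). The mesoderm call was lost with RLE scaling (adjusted p = 0.0545), with library sizes only (0.136), after thinning (0.0911) and without pseudogenes and mitochondrial genes (0.0538). That of other Polycomb regulators was lost with library sizes only (0.0585), after thinning (0.14) and under the stricter filter (0.302).

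Single genes differed too. The fold in EBd2 was at least 30.1 times that in ES cells for Msln, at least 14.1 times for Krtdap and at least 9.89 times for Cnga4. From low counts in fl/fl EBd2, the ratio of folds was 330 for Sprr2a2, 266 for Sp5 and 140 for Mageb4. More negative effects in EBd2 were seen for Bcl11a (-4.38), Etv2 (-3.88), Car14 (-3.86), Brsk2 (-3.57), Insm1 (-3.55), Vat1l (-3.27), Otx2 (-3.08), Fdps (-2.26), Dnmt3b (-2.21), Fgf5 (-1.59), Kdm2b (-0.79), Cdkn1b (-0.63), Pou5f1 (-0.43) and Skp1a (-0.24). More positive effects were seen for T (5.22), Gata6 (2.65), Tbx3 (2.48), Col4a1 (2.28), Cdkn1a (1.03), Nanog (0.68), Eed (0.43), Ccne1 (0.32), Ezh2 (0.30) and Zfp42 (0.19). The Fgf5 call was lost without the KO ES cell library of lot 1 (-0.52, adjusted p = 0.579) and after thinning (-0.89, adjusted p = 0.339). The Zfp42 call was lost with lots as blocks (0.374) and without the fl/fl ES cell library of lot 2 (0.0702), the KO ES cell library of lot 12 (0.0757), the fl/fl EBd2 library of lot 12 (0.126), or the KO EBd2 library of lot 1 (0.0624) or lot 2 (0.0506).

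Hox genes were higher in EBd2 labelled KO, as were feeder markers, so fibroblast RNA was weighed as a source. Of the 27 called Hox genes, 15 were also higher than in ES cells labelled KO, from which the median feeder marker fell by 1.28. Carried-over fibroblasts are thus argued against as the whole source of their reads in EBd2 labelled KO. These 15 genes were picked for that rise. The median feeder marker fell further in fl/fl (-2.99), so a fibroblast part of the gap between genotypes stays open. As a set, the 29 measured Hox genes had a median change from KO ES cells to KO EBd2 of 1.10 (quartiles 0.43 to 1.68), against -1.28 for the 19 feeder markers (quartiles -2.28 to -0.2; two-sided permutation test over genes, which are not independent, p = 1e-05, the lowest that 100000 permutations give). The other 12 called genes were not tested apart, so a fibroblast share in them stays open. Scaling by library sizes only shifted the median of all genes by 0.23, little against the Hox median of 2.97, which became 3.19. The choice between TMM and library sizes thus did not make the rise. A difference between clones, and an effect of the labelled genotype itself, remain open and untested.

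Cholesterol synthesis genes were higher in ES cells and lower in EBd2 labelled KO, though the ES cell call did not hold with an estimated correlation (camera adjusted p = 0.0888). The fall in EBd2 had a median of -1.08, and of -0.85 with library sizes only, which shifted the median of all genes by 0.23. The choice between TMM and library sizes thus did not make the fall. With all libraries thinned to one depth the median interaction was -1.24. Total counts were similar between genotypes within each stage, so thinning could not decide whether depth played a part. Medium, density and clone differences are not given in the sources used here, and with the labelled genotype they stay open and untested.

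Skp1a counts were largely kept in libraries labelled KO. Fibroblast RNA is argued against as the whole source. From KO ES cells to KO EBd2, the summed CPM of the 19 feeder markers fell to 31.8% (bootstrap over markers, 95% interval 21.6% to 52.8%), while Skp1a kept 78.8%. This takes the share of Skp1a in fibroblast RNA as constant, and a fibroblast part of the Skp1a reads stays open. A single exchanged library is argued against, since within each stage the narrowest spread between genotypes was at least 1.75 times the widest spread within a group of that stage. A deletion that leaves counted transcripts may account for the 72.8% left in EBd2, but counts per gene cannot tell this apart from an undeleted gene. A mixture of deleted and undeleted cells was not tested.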

How the results depend on the processing

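Library size only, the test beyond 1.5-fold, the fit without pseudogenes and mitochondrial genes and thinning were chosen after the data had been seen. For the 3926 genes called in ES cells, leaving out 1 library gave 1909 to 3958, lots 1, 2 and 12 as a replicate block 2236, thinning 2080 and the test beyond 1.5-fold 17. The 205 genes at least 2-fold changed became 386 with no filter, 73 under the stricter filter, 73 by DESeq2, 127 with the replicate block, 14 beyond 1.5-fold and 114 to 219 without 1 library. The test beyond 1.5-fold called 3910 genes in EBd2, 3043 for stage in fl/fl, 3733 for stage in KO and 2331 for the interaction. At least 2-fold changes under the stricter filter, which tests fewer genes, numbered 2014 in EBd2, 1597 for stage in fl/fl and 1704 for stage in KO. The genotype correlation became 0.379 under the stricter filter, 0.0405 with the replicate block, 0.348 without pseudogenes and mitochondrial genes, 0.402 with 4 libraries per fit and 0.209 to 0.276 without 1 library. The stage correlation became 0.527, 0.303 and 0.556 under the stricter filter, the replicate block and 4 libraries, and 0.367 to 0.451 without 1 library. Directions turned for the histone list in EBd2 under the stricter filter (0.27, adjusted p = 0.96), and with library sizes only for Zfp42 (0.18), Suz12 (0.15) and Jarid2 (0.0774) in EBd2. Skp1a was not called beyond 1.5-fold in ES cells (-0.22) or EBd2 (-0.46), with adjusted p = 1, as both changes are smaller than 1.5-fold. The replicate block pulls both correlations down, since the estimated difference between lots 2 and 12 enters the compared effects with opposite signs. How much of each drop this makes was not tested, nor was the cause of the other differences between settings. Over all alternatives, the status of 215 results on named genes, called or not, was kept 3925 times. A call was lost 99 times and gained 18 times, and 3 times the direction reversed with a call in either fit. Sizes of change were not compared. For 150 list results the numbers kept, lost, gained and reversed were 2400, 69, 45 and 1. Lists have no values under DESeq2 or the test beyond 1.5-fold. A group left with 1 library was assumed to vary like the others. The lots do not pair the libraries, so a call lost with the block is not read as a weaker effect. The lower depth of EBd2 limits the calling of low genes there.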

Other observations

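The gene families and the hypotheses here were chosen after the data had been seen, and so were their tests. Gene families defined by symbol prefix also moved in EBd2 labelled KO. Among 171 families with at least 10 measured genes, collagens had 28 higher and 3 lower of 41 (median 1.76, camera adjusted p = 2.16e-05, and adjusted p = 0.321 with an estimated correlation). Some collagens are feeder markers, and 17 of the 19 feeder markers were higher as well (median 1.93). Keratins had 13 higher and 0 lower of 17 (median 2.40), Wnt ligands 14 and 0 of 15 (median 2.36), and clade B serpins 13 and 0 of 14 (median 2.61). Their camera adjusted p values were 6.52e-05, 0.000313 and 0.000978, each 0.321 with an estimated correlation. Translation initiation factors had 6 higher and 42 lower of 54 (median -0.36, camera adjusted p = 3.05e-05, and 0.437 with an estimated correlation), and the Mcm replication helicase genes 1 and 9 of 10 (median -0.37, camera adjusted p = 0.0167, and 0.437 with an estimated correlation). In ES cells, keratins had 8 higher and 0 lower of 17 (median 0.79, camera adjusted p = 2.35e-06, and 0.364 with an estimated correlation). Collagens (14 higher and 0 lower), Wnt ligands (5 and 0), translation initiation factors (2 and 24) and Mcm genes (0 and 6) were called there too. Their camera adjusted p values were 0.000509, 0.00163, 0.000263 and 0.00969, each 0.364 with an estimated correlation. The families named are a selection, and others were called at each stage. With library sizes only, the EBd2 medians of translation initiation factors and Mcm genes shrank to -0.13 and -0.14, so most of each fall rests on the scaling. The EBd2 medians of the other families named here kept their sign, while those of some unnamed families changed it.

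One hypothesis was that embryoid bodies labelled KO differ from fl/fl embryoid bodies through delay alone, along a course on which each gene moves in one direction. Of 3245 genes changed at least 2-fold from KO ES cells to KO EBd2, 233 were called in the opposite direction in fl/fl, 1709 in the same direction and 1303 not at all. The opposite call in fl/fl needed no minimum fold, and false calls or fibroblast RNA among the 233 genes were not tested apart. These genes therefore do not decide whether delay is the whole difference on such a course. A course on which genes rise and fall again was not tested.

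A further hypothesis was that the Hox and Wnt target changes reflect a shift toward a posterior axial identity. In a list of 15 caudal epiblast and tailbud genes, of which 13 were measured, 9 were higher and 2 lower in EBd2 labelled KO (9 and 2 adjusted over the list alone; median 1.08, camera adjusted p = 0.0204, and 0.128 with an estimated correlation). Nkx1-2 (6.99 ± 0.40), Cdx2 (5.35 ± 0.26), Wnt5b (2.61 ± 0.24) and Wnt8a (2.36 ± 0.14) were higher, while Fgf4 (-0.73 ± 0.04) and Cyp26a1 (-0.48 ± 0.15), which marks the tail bud, were lower. The 9 members go with such a shift, but the list was written after the data had been seen, with the Hox result known. Nkx1-2 was among the largest rises from ES cells to EBd2 in cells labelled KO. The Wnt members belong to a family with 14 of 15 genes higher in EBd2 labelled KO. The list is thus no independent test, and its call does not hold with an estimated correlation.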
